A study of Rhodonia placenta with 23 samples.

How the data were processed

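Total RNA of mycelium from wood wafers was labelled with Cy3 as cDNA and hybridised to single-colour NimbleGen arrays, one sample per array, per the labels' protocols. The cultures had grown for 10 days on agar before the wafers were inoculated and were kept at 22 °C. The design text states that 60-nucleotide probes were used, 10 per gene, and that NimbleScan version 2.4 extracted the scans. It gives 9959 genes targeted out of 12438 gene models, whereas each file holds values for all 12438 models. It plans 24 arrays, and 23 samples were analysed here.

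The authors deposited a file per array with intensity values on a linear scale, made by RMA per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects background, equalises the distribution of probe values over arrays and fits a value per probe set. Per the file headers each gene model has 2 blocks of 5 probes, with a value each. The authors also deposited a series table of log2 values, which equalled the mean log2 of both blocks within 2.8e-06 for each of the 12435 models it lists. It left out 3 models. The design text speaks of log2 conversion, quantile normalization and averaging of probes in GeneSpring, and the order of these steps relative to RMA is not given in the sources used here. Equalised distributions make the total signal of all arrays nearly alike, so a change in the overall amount of fungal RNA in the wood would not be seen.

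Here the log2 of each block was taken and the 2 blocks were averaged per model, with no further normalization and no filter. A robust SD of the mean of the 2 blocks ran from 0.033 to 0.082 on the log2 scale, with a median of 0.047. It was taken from the block difference, less each model's mean difference over arrays, and estimates the measurement error within an array. The log2 median per array lay between 11.61 and 11.71. A row of 16182 random control probes gave the background, and 2 models lay below 2 times that value on every array. No depth applies to arrays, and the number of arrays limits the precision.

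Samples were grouped by substrate and day as in their titles, which agree on this with their source names and characteristics. The description of the third 20-day sample of substrate A gives 10 days, and the sample was kept at 20 days, with the other reading as an alternative. The protocol text places a failed replicate of substrate B at 10 days, while the titles show 3 samples of B at 10 days and 2 at 20 days, and the titles were followed. By their array and image names the samples came from 2 slides, 11 arrays on one and 12 on the other. The main fit had no term for slide, which entered only in the alternatives below.

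A linear model with one mean per group was fitted over all 23 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes), and comparisons were contrasts of group means. This gave 14 residual degrees of freedom and 3.53 prior degrees of freedom. P-values were adjusted per comparison with the Benjamini-Hochberg method, and a model was called at an adjusted p under 0.05. Fold changes are on the scale of RMA values. Means over substrates or days weight them equally. The interaction of substrate and day was tested with a moderated F test on 4 contrasts. The code was tested on simulated data with a single spread per model, pooled over the real groups, and errors independent between models and arrays. Differences in spread between groups and arrays that deviate together across models were not simulated. The shares below therefore check the code and do not give the power or the false calls of the real comparisons. For substrate A against B over all days, 93% of 100 models changed by 0.5 on the log2 scale and 100% of 100 changed by 1 were called, with 9 false calls. For 30 against 10 days over the substrates the shares were 91% and 100%, with 8 false calls. For A against B at 10 days they were 80% and 95%, with 9 false calls, and at 30 days 88% and 94%, with 6 false calls.

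The models named were chosen by a rule set before the data were examined. In each of the comparisons of 30 with 10 days, of A with B over all days and of A with B at each day, they are the 2 called models with the largest log2 difference in each direction. They had to differ in the same direction in each substrate or day, or, at a single day, to show no overlap between replicates. In other comparisons up to 2 per direction are given. The annotation column of the files was empty for every model and no table of gene names was used here. The 21 gene lists fixed beforehand by product names (among them wood-degrading enzymes, iron uptake and ribosomal proteins) therefore had no members and were not tested. The list of models lower on A at 10 days was chosen from the data and followed in other arrays with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over 8 contrasts.

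The alternatives set before the data were examined were the series table, quantile normalization, median centring, leaving out the dimmest models (mean log2 under 10.99, which kept 9328), an intensity trend with a robust prior, array weights, slide as a fixed or random block or one slide alone, the replicate number as a block with or without slide, a fit of only the groups compared, a 2-fold threshold, the other reading of the doubtful sample, and leaving out each array. Added after seeing the data were each probe block alone, median ratio centring, the fit without A replicate 3 and B replicate 2 at 30 days, and the fit without 30 days. Figures were drawn with matplotlib 3.10.9, and files were read with pandas 2.3.3 in Python 3.11.15.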

Results

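Transcript levels of the brown-rot fungus Rhodonia placenta (Postia placenta), strain MAD-698-R, were measured while it grew on wood wafers of poplar. Brown-rot fungi remove the carbohydrate of wood and leave a modified lignin behind. Wafers came from 3 poplar genotypes: substrate A with high lignin and low glucose, substrate B with low lignin and high glucose, and substrate C with contents of both near the average of the tree population. Mycelium was collected after 10, 20 or 30 days, which gave 9 groups and 23 arrays. Substrates A and B had 3 arrays per time, except for B at 20 days with 2, and substrate C had 2 per time. The labels describe the replicates of a group as separate cultures. Each array gave a value for 12438 gene models, and the median intensity per array lay between 3134 and 3342, against 37 to 39.3 for random control probes. No more than 7 models on any array lay below 2 times the random control value. The number of arrays limits the precision. The files do not pair the model identifiers with gene names or products, so models are given by identifier, at most 2 per direction in each comparison, and no gene family could be described.

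Most arrays of substrate A lay apart from most arrays of the other woods. The first principal component held 61.1% of the variance over all models and the second held 10.7%. On the first, 7 of the 9 arrays of A scored -15.9 or lower. The other arrays of A, replicate 3 at 10 days and at 30 days, scored -5.4 and -2.3, while B at 30 days replicate 2 and C at 30 days replicate 1 lay further to the side of A, at -16.8 and -6.7. Differences between the 9 groups made up 66.7% of the variance, with 39% between substrates and 16.3% between days, and 33.3% lay between arrays of one group. These shares were not corrected for the number of groups, and groups formed at random would also hold part of the variance. Replicates were close in some groups, with a median SD of 0.067 on the log2 scale over the 3 arrays of A at 20 days, and further apart in others, with 0.134 for A at 10 days. Arrays of one group correlated at r = 0.951 for B at 20 days and r = 0.956 for C at 30 days, 2 arrays each, across models. The array with the closest profile belonged to the same group for 7 of the 23 arrays and to the same substrate for 12.

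**Figure D1:**
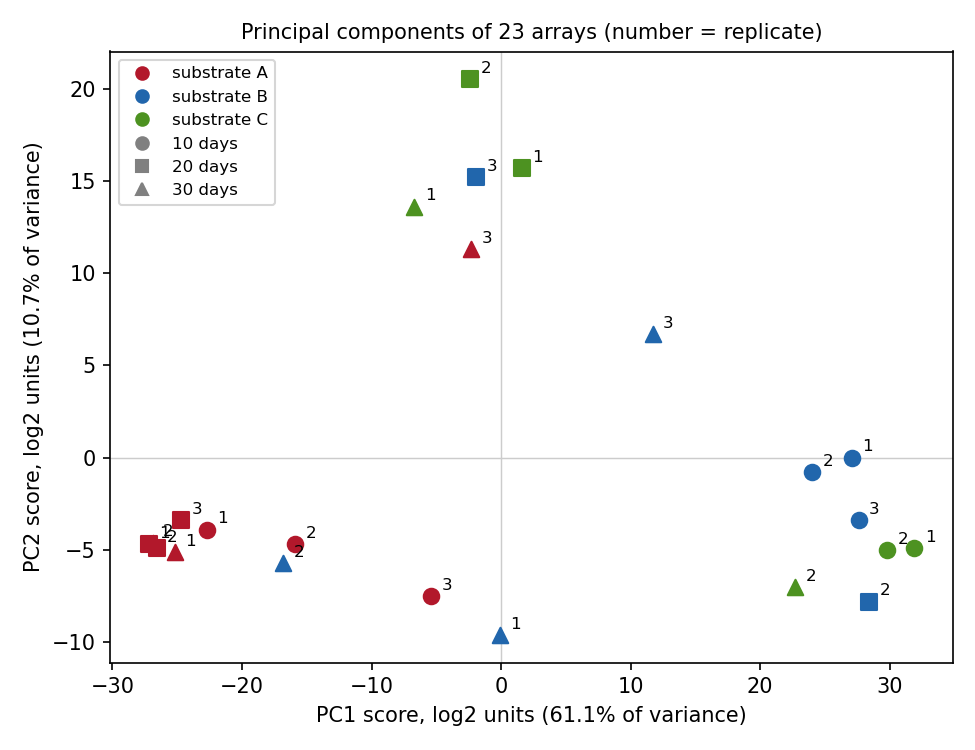
Scores of the 23 arrays on the first (horizontal axis) and second (vertical axis) principal components of the log2 values, with substrate as colour, incubation time as symbol and the replicate number beside each point. Most arrays of substrate A lie at the left, arrays of B and C at 10 days lie at the right, and several groups at 20 and 30 days are spread over the plot.

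The substrate with high lignin was set against the one with low lignin over all 3 times. Each substrate was a single poplar genotype, so lignin, glucose and other traits of the genotype cannot be told apart. The replicates are cultures of the fungus, so the tests concern these woods and not lignin content in general. On substrate A, 208 gene models were at least 2-fold lower than on substrate B, and none was called at least 2-fold higher. The model with the greatest drop, 125346_estExt_Genewise1_C_100084, was 5.51-fold lower on A (log2 difference -2.46 ± 0.53, SE, adjusted p = 0.00158). Its log2 level on A was 10.31 ± 1.48 (SD, n = 3) at 10 days and 9.16 ± 0.24 (SD, n = 3) at 20 days, while on B it was 13.15 ± 0.04 (SD, n = 3) and 12.71 ± 0.47 (SD, n = 2). At 30 days the arrays of this model overlapped more, with 10.49 ± 2.26 on A and 11.48 ± 1.6 on B (SD, n = 3 each). Model 113926_estExt_Genewise1Plus_C_1130023 was 4.72-fold lower (-2.24 ± 0.43, SE, adjusted p = 0.00089). Increases on A were small: the greatest were 1.36-fold each, for 102362_fgenesh3_pg_23_2 (log2 difference 0.45 ± 0.1, SE, adjusted p = 0.00154) and 104717_fgenesh3_pg_161_13 (0.44 ± 0.09, SE, adjusted p = 0.00124).

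Many smaller differences lay behind these. In all, 4965 models were higher and 2406 lower on A than on B (limma, adjusted p under 0.05), with a median log2 difference of 0.20 among those higher and -0.36 among those lower. This split depended on the scaling, since centring each array on its median ratio to the mean profile gave 2710 higher and 3301 lower, with 247 models at least 2-fold lower and none at least 2-fold higher. The median difference over all models was 0.087 as deposited and 0.015 after that centring. Adding slide as a block gave 7541 models, and within slide 2, which alone held both substrates at every time, 1549 were called over 6 arrays of A and 5 of B, among them 104717_fgenesh3_pg_161_13 but none of the other 3 named models. The count at least 2-fold lower was 130 without B at 20 days replicate 2 and 333 without the 30-day arrays.

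The difference between A and B was present at 10 days, when 338 models were at least 2-fold lower on A and none was at least 2-fold higher. Model 127073_estExt_fgenesh3_pg_C_330066 was 7.77-fold lower on A (10.44 ± 0.21 against 13.4 ± 0.22, SD, n = 3 each, adjusted p = 0.00885). Model 91204_fgenesh3_pg_39_22 was 7.49-fold lower (8.63 ± 0.77 against 11.53 ± 0.29, SD, n = 3 each, adjusted p = 0.00317). The models with the greatest increase on A were 103452_fgenesh3_pg_4_64, 1.96-fold higher (adjusted p = 0.0189), and 103846_fgenesh3_pg_12_66, 1.77-fold higher (adjusted p = 0.012). Over all models 2988 were higher and 2055 lower on A, or 1899 and 2596 after median ratio centring. All 3 arrays of A lay on one side of all 3 of B for 51.5% of models, where chance gives 10%. The share was 60.6% against 20% at 20 days and 13.2% against 10% at 30 days. Models are not independent, so these shares are not a test. Adding slide as a block gave 5440 models. Within slide 1, with 2 arrays of A and 1 of B, the call was made for 2 models, and within slide 2, with 1 of A and 2 of B, for 1067; differences on the separate slides correlated at r = 0.73 across models. The count was 3271 without B at 10 days replicate 1, and the number at least 2-fold lower was 210 without A at 10 days replicate 1. One model was called at least 2-fold higher with slide as a block, without A at 10 days replicate 2 and without B at 10 days replicate 1, and 3 were without A at 10 days replicate 3. The call for 103452_fgenesh3_pg_4_64 was lost without A replicate 2, B replicate 2 or B replicate 3 at 10 days and with the third 20-day array of A placed at 10 days, and that for 103846_fgenesh3_pg_12_66 without B replicate 2; neither these nor the 2 lower models were called within a single slide.

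At 20 days 252 models were at least 2-fold lower on A than on B and none at least 2-fold higher. The greatest drops were again those of 125346_estExt_Genewise1_C_100084, 11.7-fold lower (-3.55 ± 0.99, SE, adjusted p = 0.0337), and 113926_estExt_Genewise1Plus_C_1130023, at -3.33 ± 0.81 on the log2 scale (SE, adjusted p = 0.0251). Models 55897_e_gw1_132_17_1 and 48175_e_gw1_205_4_1 were 1.55-fold and 1.49-fold higher (adjusted p = 0.046 and 0.0428), and neither call held after median ratio centring. The comparison of 3 arrays with 2 called 860 models higher and 895 lower, or 194 and 1164 after that centring. The total of 1755 moved by over 1.5 times on the loss of any of 6 arrays: it was 44, 25 and 22 without A replicate 1, 2 and 3 at 20 days, 63 without B replicate 2, 3646 without B replicate 3, and 1164 without B at 10 days replicate 2. The number at least 2-fold lower was then 21, 12 and 11 without the 3 A arrays in turn, 39 without B replicate 2 and 600 without B replicate 3. Both named lower models lost their call without any of the 3 A arrays or without B replicate 2, and both named higher models lost it in those cases too. The fit with slide as a block called 2312 models, and within slide 2, with 2 arrays of each substrate, 1 was. With the third A array placed at 10 days, as its description has it, 63 were called.

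At 30 days limma called no model between A and B. The smallest adjusted p was 0.0604, and 1388 models had an unadjusted p under 0.05 where chance gives 622. The 95% interval of the difference reached 0.20 on the log2 scale to either side for the median model and 0.37 for 9 models in 10. It rests on the variance pooled over all groups and is not specific to 30 days. The median SD was 0.122 for B and 0.095 for A at 30 days, against 0.072 and 0.134 at 10 days. The trend and robust form of limma called 2 models, array weights called 739, and within slide 2, with 3 arrays of A and 1 of B, 4 were called. Leaving out one array gave 83 models without A at 30 days replicate 3, 15 without either B array at 20 days, 11 without either C array at 30 days, 4 without either C array at 10 days and 1 without B at 30 days replicate 1. With slide as a block the count was 0.

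The 338 models at least 2-fold lower on A than on B at 10 days were followed at 20 and 30 days. Arrays of those days did not enter their fold change but did enter the pooled variance of the test that chose them. At 20 days all 338 were lower on A than on B, with a median log2 difference of -1.19, and 196 of them passed the test. That median was -0.76 and -1.59 without replicates 2 and 3 of B at 20 days, and -0.65 for the list chosen within slide 2. At 30 days 316 were lower, with a median of -0.37, and none passed. The 30-day median was -0.66 with array weights. Without replicates 1, 2 and 3 of A at 30 days it was -0.25, -0.24 and -0.63, and it was -0.64 and -0.10 without replicates 2 and 3 of B. Against substrate C, their median on A was -0.71 at 20 days and -0.72 at 30 days, with 313 and 336 of 338 lower, of which 58 and 0 passed the test. These medians moved with single arrays of C: without replicates 1 and 2 of C the value was -0.52 and -0.90 at 20 days, and -1.15 and -0.25 at 30 days. Their mean log2 level stayed low on A, at 11.22 ± 0.37, 10.93 ± 0.01 and 11.22 ± 0.5 (SD, n = 3 each) at 10, 20 and 30 days. On B it was 12.65 ± 0.03 (SD, n = 3), 12.18 ± 0.53 (SD, n = 2) and 11.66 ± 0.52 (SD, n = 3), and on C 12.62 ± 0.05, 11.8 ± 0.23 and 11.99 ± 0.58 (SD, n = 2 each). A rotation test (fry) for the list between A and B gave an adjusted p of 0.0223 at 20 days and 0.255 at 30 days over 8 contrasts, and between A and C 0.0908 at both times. A camera test with a preset correlation gave adjusted p = 2.77e-60 at 20 days, but adjusted p = 0.13 with an estimated correlation, as it did at 30 days and between A and C at both times. Across all 12438 models, which are not independent replicates, the difference between A and B at 10 days correlated with that at 20 days (Pearson r = 0.89, but 0.71 without B at 20 days replicate 2 and 0.70 within slide 2) and with that at 30 days (r = 0.65), where no array is shared. The latter was 0.76 with array weights, 0.53, 0.51 and 0.76 without replicates 1, 2 and 3 of A at 30 days, and 0.75 and 0.33 without replicates 2 and 3 of B. Within slide 2 this correlation was -0.03, and the median of the list chosen within that slide was 0.10 at 30 days.

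**Figure D2:**
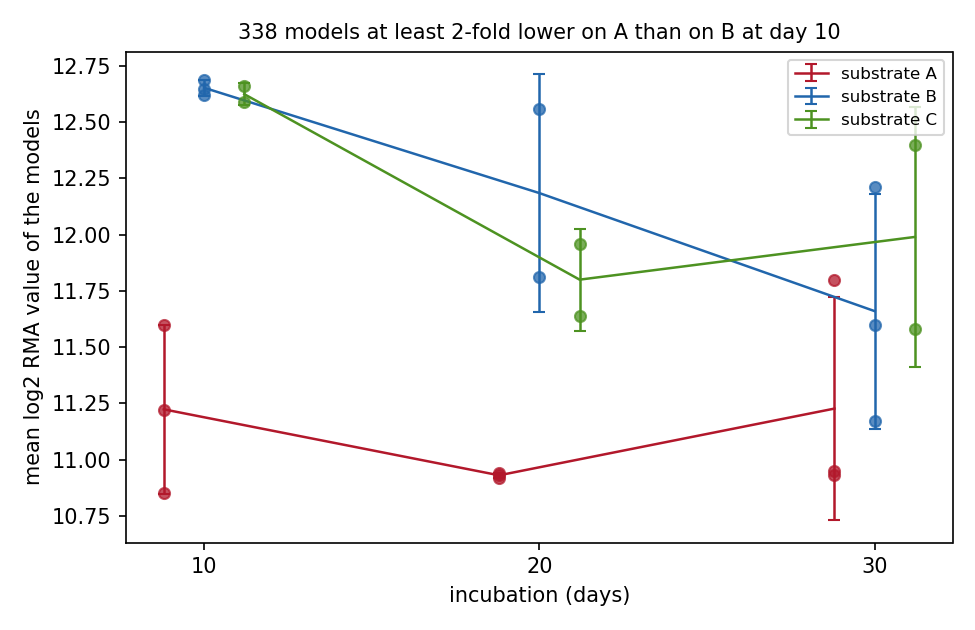
Mean log2 RMA value (vertical axis) of the 338 gene models that were at least 2-fold lower on substrate A than on substrate B at 10 days, against incubation time in days (horizontal axis). Each point is an array, lines join group means and bars are SD over 2 or 3 arrays. The points at 10 days for A and B served to choose the models; at 20 days the 3 arrays of A lie between 10.92 and 10.94 and those of B at 11.81 and 12.56.

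**Figure D3:**
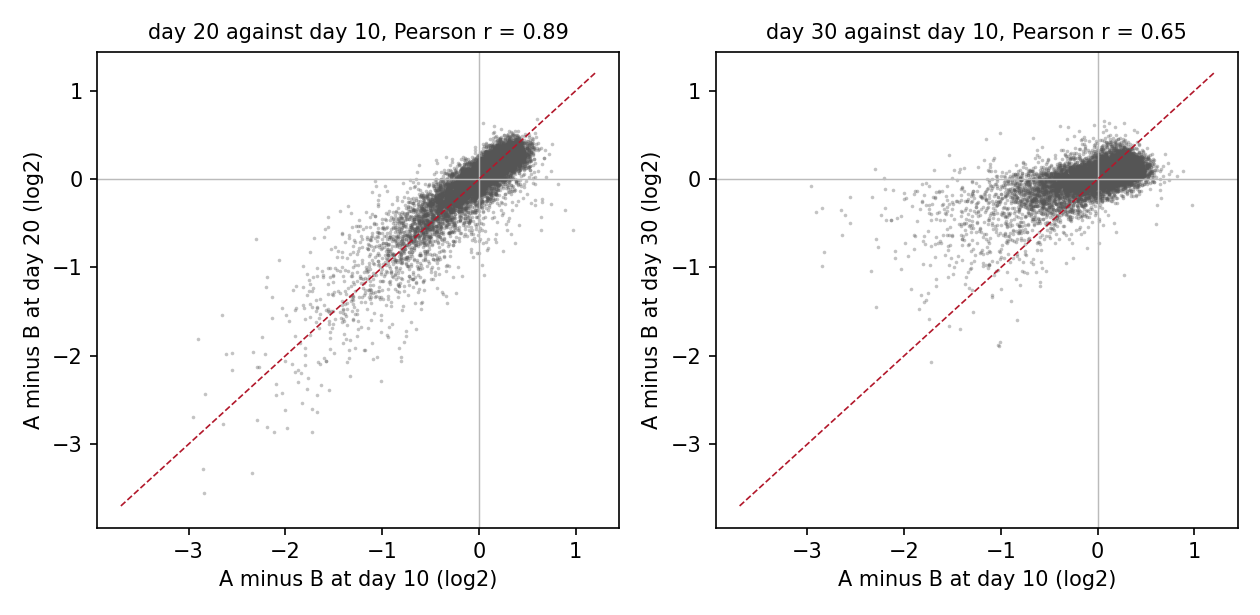
Log2 difference A minus B of each of the 12438 gene models at 20 days (left) and 30 days (right), on the vertical axes, against that at 10 days on the horizontal axes. The dashed line marks equal differences; points fall near it at 20 days (r = 0.89) and closer to 0 than the line at 30 days (r = 0.65).

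The wood near the average, substrate C, was set against A and B in turn. Over the 3 times 182 models were at least 2-fold lower on A than on C and none at least 2-fold higher. In all 5588 models were higher and 1972 lower, or 2488 and 2974 after median ratio centring, which took the median over all models from 0.11 to 0.017 and gave 237 models at least 2-fold lower. With slide as a block 5631 were called, of which 5498 were among the 7560 called without it. No slide held A and C at all times. The number at least 2-fold lower was 121 without C at 30 days replicate 2.

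Between substrates B and C limma called no model over the 3 times. An unadjusted p under 0.05 was reached by 659 models, close to the 622 that chance gives, and the trend and robust form called 0. The 95% interval of the difference reached 0.13 on the log2 scale to either side for the median model and 0.25 for 9 models in 10. At 10 days 5 models passed, 2 higher and 3 lower on B. Among them 21733_gw1_43_10_1 was higher by 0.92 ± 0.13 (SE, adjusted p = 0.0106) and 127242_estExt_fgenesh3_pg_C_160083 lower, at -0.71 ± 0.12 (SE, adjusted p = 0.0423). These 2 were chosen after their values were seen.

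To ask how expression changed as decay went on, 30 days were set against 10 days over the 3 substrates. The greatest drops with time were those of 118723_estExt_Genewise1_C_180160, 2.82-fold (-1.49 ± 0.37, SE, adjusted p = 0.0214), and 129056_estExt_fgenesh3_pg_C_1440023, 2.75-fold (-1.46 ± 0.34, SE, adjusted p = 0.0197), among models that fell on each substrate. The first stood at 13.07 ± 0.31 on B at 10 days and 10.53 ± 0.33 at 30 days (SD, n = 3 each), while on A it was 10.42 ± 0.52 and 10.18 ± 0.07 (SD, n = 3 each). On C it was 13.14 ± 0.87 and 11.43 ± 2.13 (SD, n = 2 each). The greatest rises were those of 91873_fgenesh3_pg_26_45, 1.43-fold (0.51 ± 0.11, SE, adjusted p = 0.0186), and 105891_fgenesh3_pg_66_29, 1.41-fold (0.49 ± 0.12, SE, adjusted p = 0.0209). In all 1745 models rose and 713 fell, 20 of them at least 2-fold, and none rose 2-fold. The split was 461 and 1152 after median ratio centring, 1059 and 900 after median centring and 1006 and 821 after quantile normalization. Single arrays of C decided the count, which was 8 without C at 30 days replicate 1 and 75 without C at 10 days replicate 2, and all 4 named calls were lost in both cases. The number at least 2-fold lower was 1 without C at 30 days replicate 1 and 79 without replicate 2, when 2 models were 2-fold higher. It was 34 and 9 without A at 10 days replicates 1 and 3, 12 and 13 without B at 10 days replicates 1 and 3, 11 and 9 without C at 10 days replicates 1 and 2, 10 without A at 30 days replicate 1 or 2, and 9 without B at 30 days replicate 2. The count of all calls was 1008 and 1389 without B at 10 days replicates 1 and 3, 800 and 759 without A at 30 days replicates 1 and 2, and 1076 without B at 30 days replicate 2. The fit with slide as a block called 2407 models, and no slide held all 6 groups.

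From 10 to 20 days 729 models rose and 468 fell over the 3 substrates, 36 of the latter at least 2-fold. The split was 245 and 747 after median ratio centring, 553 and 605 after median centring and 420 and 551 after quantile normalization. The count of 1197 dropped to 141 with slide as a block, 138 of them shared, and no slide held all 6 groups. It was 35 without B at 20 days replicate 3 and 3471 without replicate 2. Without B at 10 days replicates 1, 2 and 3 it was 248, 546 and 437, without C at 10 days replicates 1 and 2 it was 262 and 202, and without A at 20 days replicates 1, 2 and 3 it was 256, 221 and 503. It was 259 without C at 20 days replicate 1 and 769 without A at 30 days replicate 2. The number at least 2-fold lower was 13 with slide as a block and 4 without B at 20 days replicate 3. Without replicate 2 of B, 116 models differed at least 2-fold, 11 of them higher at 20 days. The number lower was 18 without B at 10 days replicate 1, 11 and 16 without C at 10 days replicates 1 and 2, 20, 17 and 22 without A at 20 days replicates 1, 2 and 3, and 21 and 19 without C at 20 days replicates 1 and 2. With the third 20-day array of A placed at 10 days, as its description has it, 347 models were called. Between 20 and 30 days limma called no model, with 957 at an unadjusted p under 0.05, and the trend and robust form called 0.

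On single substrates, the change from 10 to 30 days was called for 99 models that rose and 418 that fell on B, 75 of the latter at least 2-fold. Median ratio centring gave 44 and 776. On A limma called no model, with 700 at an unadjusted p under 0.05, and its trend and robust form called 0. On C it called 127242_estExt_fgenesh3_pg_C_160083, which fell by 1.03 on the log2 scale (± 0.13, SE, adjusted p = 0.00358) from 11.96 ± 0.09 to 10.94 ± 0.14 (SD, n = 2 each), and 2565 models had an unadjusted p under 0.05. That call was lost without C at 30 days replicate 1. Across models the change on B correlated with that on C at r = 0.75 and with that on A at r = 0.11. The latter was 0.32 and -0.18 without A at 10 days replicates 1 and 3, and -0.09, -0.12 and 0.46 without A at 30 days replicates 1, 2 and 3. It was 0.05 without B at 30 days replicate 3, 0.36 with array weights and 0.36 within slide 2. The count for B was 518 with slide as a block, 0 within slide 1 and 8 within slide 2, and changes on the separate slides correlated at r = 0.74 across models. It was 21, 61 and 137 without B at 10 days replicates 1, 2 and 3, and 28, 38 and 1701 without B at 30 days replicates 1, 2 and 3. The number at least 2-fold lower was 7, 20 and 25 without the B arrays at 10 days in turn, and 7, 7 and 226 without those at 30 days. Leaving out arrays of other groups gave 337 and 321 (A at 20 days replicates 1 and 2), 924 (either B at 20 days) and 795 (A at 30 days replicate 3). A count on B and none on A does not show that the substrates differed in their change with time, and the test of that difference follows.

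Whether the difference between A and B itself changed with time was tested as an interaction. From 10 to 30 days 3 models passed. In model 98247_fgenesh3_pg_7_88 the difference A minus B rose by 0.67 ± 0.1 (SE, adjusted p = 0.0353), from levels of 11.5 ± 0.08 on A and 12.14 ± 0.06 on B at 10 days to 11.62 ± 0.09 and 11.57 ± 0.07 at 30 days (SD, n = 3 each). In 127723_estExt_fgenesh3_pg_C_250022 it rose by 0.74 ± 0.12 (SE, adjusted p = 0.0389), and in the other model by 0.48 ± 0.08 (SE, adjusted p = 0.0389). With slide as a block none of the 3 was called, and the 1 model called within slide 2 was none of them and changed the other way. The count was 0 when any B array at 10 days, any C array at 20 or 30 days, A replicate 1 or 3 at 10 days, A replicate 1 or 2 at 20 days, A replicate 1 or 3 at 30 days or B replicate 1 or 2 at 30 days was left out. It was 1 without A at 30 days replicate 2, 9 without either B array at 20 days and 571 without B at 30 days replicate 3. From 10 to 20 days no model passed, with 343 at an unadjusted p under 0.05, and the trend and robust form called 0. A test over all 4 interaction terms of substrate and day called 0 models with limma, with 979 at an unadjusted p under 0.05, and 0 with its trend and robust form.

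The other pairs of groups gave the following counts. Between A and C 5722 models were called at 10 days, 375 at 20 days and 0 at 30 days, when 2381 had an unadjusted p under 0.05. Between B and C none was called at 20 or 30 days, with 491 and 384 unadjusted. From 10 to 20 days 186 models were called on C, 36 of them at least 2-fold lower and 8 at least 2-fold higher, and none on A or B, with 942 and 699 unadjusted. From 20 to 30 days 2 were called on B, both lower at 30 days, namely 122573_estExt_Genewise1_C_1390015 (-1.86 ± 0.25, SE, adjusted p = 0.0122) and 90226_fgenesh3_pm_4_25 (-0.81 ± 0.12, SE, adjusted p = 0.0137). Both calls were lost without B at 30 days replicate 2, with array weights, with replicate as a block, alone or beside slide, and in a fit of only the groups compared. The second was also lost without B at 20 days replicate 3, without B at 30 days replicate 1, within slide 2 and on probe block 1 alone. None was called on A or C in that interval, with 195 and 535 unadjusted. Each of these counts of 0 was also 0 with the trend and robust form of limma.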

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

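The tests of slide, of measurement error, of exchanged labels and of a shared RNA sample, and both tests of the one-sided differences, were chosen after the results were seen. The tests of array position and of the axes of variation, and the counts over other splits of the arrays, were set before their results were seen.

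The difference between substrates A and B changed between 10 and 30 days in 3 gene models by the interaction test, and the change of A minus B was 0.67, 0.48 and 0.74 on the log2 scale, the first in 98247_fgenesh3_pg_7_88 and the last in 127723_estExt_fgenesh3_pg_C_250022. As many models were called by 4 of 100 splits of the arrays, the real one included. This share is just under 0.05, but it cannot test the interaction alone. The splits moved arrays between days within each substrate, so they also removed the change with time on A and on B. The count does not hold either: it was 0 with slide as a block, 0 with replicate as a block, and 0 without any one of 15 of the 23 arrays. When single arrays were left out the change itself ran from 0.63 to 0.72 in 98247_fgenesh3_pg_7_88, from 0.42 to 0.52 in the second model and from 0.70 to 0.81 in 127723_estExt_fgenesh3_pg_C_250022, so these losses are of the threshold. The highest other split called 779 models against the real 3, which points to a structure of the samples. It is the real split with the days turned round and A at 10 days replicate 3 exchanged with A at 30 days replicate 2.

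Arrays of one group stood far apart in some groups, and those at 20 and 30 days were tested. The spread was not limited to these days: A at 10 days had the highest median SD, 0.134 on the log2 scale, with correlations down to 0.958 and variance ratios from 3.2 to 9.96. The variance of the difference between arrays, relative to that expected from the disagreement of the probe blocks, was 40.4 for the pair of B at 20 days, 17.5 for the pair of C at 30 days, and 25.7 and 22 for A at 30 days replicate 3 against its partners, while the closest pair of one group had 2.16. Slide as the cause is argued against by the value of 40.4, which belongs to a pair on one slide and exceeds the 21.4 that was highest between slides. The median error of these 5 arrays was 0.042 against 0.047 over all arrays, but they were picked by a ratio that is high where this error is low. Random measurement error within an array is argued against by other values. Each of the 5 correlated at 0.992 to 0.994 with an array of another group, against 0.951 to 0.968 with the closest of its own. Error common to several arrays stays open. Position on the slide is argued against by a rank correlation of -0.03 between position gap and profile distance. Exchanged labels of A replicate 3 and B replicate 2 at 30 days cannot be told apart from real differences between cultures: the exchange lowers the variance within groups by 11.3%, rank 3 of 234 exchanges, and takes the mean ratio from 17 to 6.33 in A but only from 11.1 to 8.28 in B, while another exchange (B at 20 days replicate 2 with C at 30 days replicate 1) lowers it by 23.2%. Cultures that differ along the same axes as the groups remain open too, since 70.9% of the variance within A at 30 days, B at 20 days and C at 30 days lay on the first 2 components of the other groups' means. This share was 46.8% for B at 30 days, 12.6% for A at 10 days and from 2.54% to 11.1% in the remaining groups.

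An array of A at 20 days (replicate 1) and an array of A at 30 days (replicate 2) were nearly identical. Their variance ratio was 1.28, where 1 would mean no difference beyond the disagreement of probe blocks, against 2.16 for the closest pair of one group, and they correlated at 0.998 across models. One RNA sample on both arrays is a candidate explanation, and it cannot be told apart from cultures that did not change between these days, because no pair of arrays known to share an RNA sample gives a standard. Both arrays were kept as separate samples, as labelled. No biological explanation of this pair was tested.

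Differences of at least 2-fold between A and B over all days lay one way, with 208 models lower and 0 higher on A. Single days had exceptions. At 10 days 1 model was higher and 372 were lower on A than on C, and between A and B 1 was higher with slide as a block, without A replicate 2 or without B replicate 1, and 3 were without A at 10 days replicate 3. A ceiling at the level of the brightest model is argued against, since 96.2% of models had room to rise by 4-fold or more below it. That none of these was called 2-fold higher restates the pattern. Median ratio centring could not test the scaling between arrays. It moved the median difference over all models from 0.087 to 0.015, while the largest rise of any model was 0.45. The result of 0 models at least 2-fold higher was thus settled beforehand, and 247 were called at least 2-fold lower. A constant offset alone is argued against, since it would move all models alike and the median of 0.087 was towards higher on A. Effects of the RMA step itself were not tested. Compression of fold changes by the array chemistry was not tested, and the difference in wood chemistry between the substrates stays open as an untested explanation.

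For A against B over all days the real split called 7371 models and was alone among 100 splits to reach that number, which argues against chance. The highest other split called 7260, and it was close to the real one with the names turned round, since it exchanged A and B for all but A at 20 days replicate 3, A at 30 days replicate 3 and B at 30 days replicate 2. For A against C the real 7560 was reached by 1 of 100 splits, the real one, with 4944 as the highest other. For B against C 100 of 100 splits reached the real 0, with 233 as the highest other, so the count says nothing against chance. The real 2458 for 30 against 10 days was reached by 2 of 100 splits, the real one included. The highest other, 2856, exchanged the third arrays of A at 10 and 30 days. The count was 8 without C at 30 days replicate 1 and 75 without C at 10 days replicate 2. A share of 2 in 100 on a count that single arrays decide does not exclude chance. For 20 against 10 days 1 of 100 splits, the real one, reached the 1197 calls, and the highest other had 189. With slide as a block the real split called 141, below that 189, and the other splits were not fitted with slide. For 30 against 20 days 100 of 100 splits reached the real 0, and the highest other had 300. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. A against B at 10 days called 5043, with 0 as the highest other and 1 split reaching the real count. A against B at 30 days called 0, with 729 as the highest other, in which A replicate 3 and B replicate 2 changed places, and all 10 splits reached the real count. The change from 10 to 30 days called 0 on A (highest other 42, 10 splits reaching it) and 517 on B (highest other 0, 1 split reaching it).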

How the results depend on the processing

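Alternatives that left a count within 1.5 times its value are not listed. The series table, slide as a random block (correlation within slides 0.0229) and, except at 30 days for A against B and for 30 against 10 days on C, the trend and robust prior moved no count of the comparisons further than that. The counts for A against B and A against C over all days kept their size under every alternative that uses all samples and the same threshold. The models called were not all the same. After median ratio centring 5116 of the 7371 calls for A against B and 4459 of the 7560 for A against C were shared. The cause of the other changes was not tested, except that fits on one slide, without arrays or on one probe block use fewer data. Only 2 to 7 models per array lay below 2 times the random control. Unspecific signal above that control was not assessed, so the limit set by background is not known. The gene lists fixed beforehand had no members, so their tests with estimated correlation and fry were not run. Of 877 alternative values of named models 709 stayed on their side of the threshold, 168 kept their direction but lost the call, and 0 reversed.

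By scaling, A against B at 30 days called 10 models after quantile normalization, 8 after median centring and 7 after median ratio centring instead of 0. Its interaction between 30 and 10 days called 0 and 1 after the first 2 of these instead of 3. The change from 10 to 30 days on C called 4 and 8 models after median and median ratio centring instead of 1, and median ratio centring, chosen after seeing the data, gave 1613 instead of 2458 for 30 against 10 days and 820 instead of 517 for B alone. Leaving out the dimmest models gave 8 for A against B at 30 days and 3 for the change on C, and the trend and robust prior gave 2 and 3. Array weights, which ran from 0.367 to 6.86, gave 3950 for 30 against 10 days, 2184 for 20 against 10 days (1197 as reported), 739 for A against B at 30 days, 1801 for the change on B, 2 on C and 28 for the interaction.

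Slide as a block gave 141 for 20 against 10 days and 0 for the interaction. Within slide 1 A against B at 10 days called 2 models instead of 5043, and the change from 10 to 30 days called 0 on B and 0 on C. Within slide 2 A against B called 1549 over all days instead of 7371, 1067 at 10 days, 1 at 20 days instead of 1755 and 4 at 30 days, the change on B called 8 and the interaction 1. Also within slide 2 the correlation of A minus B between 10 and 30 days turned to -0.03 from 0.65, and the median of the list of models lower on A at 10 days turned to 0.10 from -0.37 at 30 days, with 1 array of B at 30 days on that slide.

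Same-numbered replicates did not deviate together as a whole, and the labels describe separate cultures. Over 79 pairs of arrays with the same number the correlation of deviations from the group means ran from -0.5 to 0.87. Its mean was 0, and 20 pairs lay over 0.1. Between A and B it ran from -0.14 to 0 at 10 days, from -0.09 to -0.02 at 20 days and from 0.08 to 0.71 at 30 days. A pairing at 30 days alone was not tested, since the replicate block spans all groups. With the replicate block, A against B at 20 days called 919, the change on C 3 and the interaction 0. With the replicate block and slide together these were 1166, 4 and 0, and 20 against 10 days gave 106. The block left the other counts within 1.5 times.

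A fit of only the groups compared gave 844 for A against B at 20 days, 219 for the change on B, 0 on C and 1 for the interaction. With a threshold of at least 2-fold, the counts were 20 for 30 against 10 days, 36 for 20 against 10 days, 208 for A against B and 182 for A against C over all days, 338 at 10 days and 252 at 20 days for A against B, 75 for the change on B and 0 for the interaction. With the doubtful A sample at 10 days, 20 against 10 days gave 347, A against B at 20 days 63 and the interaction 7.

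Chosen after seeing the data, probe block 1 alone gave 1555 for 30 against 10 days, 925 for A against B at 20 days and 2 at 30 days, 2 for the change on C, 0 for the interaction and 1 for the test over all interaction terms instead of 0. Block 2 alone gave 754 for 20 against 10 days, 873 for A against B at 20 days and 1 at 30 days, 333 for the change on B, 10 on C and 0 for the interaction. Without A replicate 3 and B replicate 2 at 30 days, picked for their likeness to other groups, so that a greater difference between A and B is built in, 20 against 10 days gave 1872, A against B 2637 at 20 days and 799 at 30 days, the change on B 45 and the interaction 0. Without 30 days, B against C gave 1 instead of 0.

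Leaving out each array in turn, the count ran from 8 to 3675 for 30 against 10 days, 35 to 3471 for 20 against 10 days and 0 to 14 for 30 against 20 days, where the 14 came without B at 20 days replicate 2. It ran from 4968 to 7844 for A against B over all days, 5595 to 7872 for A against C and 0 to 1 for B against C. For A against B it ran from 3271 to 5300 at 10 days, 22 to 3646 at 20 days and 0 to 83 at 30 days. The change from 10 to 30 days gave 0 on A throughout, 21 to 1701 on B and 0 to 12 on C, with 0 without C at 30 days replicate 1 and 12 without replicate 2. The interaction between 30 and 10 days gave 0 to 571, that between 20 and 10 days 0 throughout, and the test over all terms 0 throughout. A group left with 1 array is assumed to vary like the others. The correlation between the changes with time on A and on B, 0.11 as reported, turned to -0.18 without A at 10 days replicate 3, -0.09 without A at 30 days replicate 1 and -0.12 without A at 30 days replicate 2, and reached 0.46 without A at 30 days replicate 3.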

Other observations

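The time test below was chosen after the values were seen, and both tests of neighbouring models were set before their results were seen.

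The difference between substrates A and B at 10 days resembled the change with time on substrate C, although the comparisons share no array. Across the 12438 models, which are not independent replicates, A minus B at 10 days correlated with 30 minus 10 days on C at r = 0.67 (Spearman 0.55) and with 20 minus 10 days on C at r = 0.68. Of the 338 models at least 2-fold lower on A than on B at 10 days, 328 were lower on C at 30 than at 10 days, with a median log2 difference of -0.61, though none of them passed the test there. That median was -0.19 without C at 30 days replicate 1 and -1.01 without replicate 2. At 20 days 307 were lower than at 10 days on C, with a median of -0.78, and 25 passed. A camera test of the list gave adjusted p = 0.13 with an estimated correlation for both times, and fry gave 0.173 at 30 days and 0.0908 at 20 days. A hypothesis is that cultures on A may lie further along a course of decay that the substrates share, and the correlation of 0.67 is in line with it. It ranged from 0.34 to 0.72 when single arrays were left out. A general axis of culture state unrelated to decay would give the same correlation, so the test does not separate these readings. A measure of wood mass loss per culture was not used here.

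Gene models whose identifiers differ by 1 in the last number changed slightly alike between substrates. If the last 2 numbers of identifiers with the fgenesh3_pg form give a stretch of sequence and a serial number along it, which the files do not state, consecutive models may be neighbours in the genome. Over 2378 consecutive pairs among 5540 models, the difference between A and B correlated at 0.17, while 1000 shuffles over all these models gave -0.06 to 0.08. The shuffles crossed stretches, so they cannot separate a likeness of consecutive models from one of whole stretches. After taking residuals on the mean signal it was 0.18, which argues against shared brightness. At serial gaps of 2 to 10 the correlation lay between 0.02 and 0.11. The 28 models of the series at least 2-fold lower were too few to show whether they group: 1 consecutive pair was lower in both members, where shuffles gave a median of 0 and up to 2. Shared probe sequence between neighbours was not tested, and no genome was used here.

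All 9 arrays of A lay above all 8 arrays of B for 30 models and below them for 41, together 0.571% of models where chance gives 0.00823%. Models are not independent, so this share is not a test.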
